A study of Mus musculus with 12 samples.

How the data were processed

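The study compared microglia of mice exposed to chronic mild stress with microglia of control mice, with 3 RNA-seq and 3 ATAC-seq samples per group. Sample titles hold the codes CO and ST, read here as control and stress, and the replicate number follows the code. Per the labels the mice were male C57BL/6Slac aged 5 months, RNA was prepared with the Direct-zol RNA Microprep and QIAseq Stranded RNA Library kits, and ATAC libraries with the TruePrep DNA Library Prep kit V2. Whether the same animals gave RNA and chromatin is not given in the sources used here.

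The RNA files hold raw counts of fragments, per the file headers, for each annotated gene and each single repeat locus in 1 table, made by the authors with featureCounts on a joined gene and repeat annotation. Per the labels the reads were aligned to mm10, and the labels name FastQC, Trim Galore, Bowtie2 2.3.4.3, SAMtools 1.9, MACS2, TopHat2 2.1.1, featureCounts 1.6.3 and DESeq2 without saying which aligner served which assay. The file headers name a later release of featureCounts than the labels. Per the file headers, counting ignored strand although the library kit marks it, so overlapping genes and antisense partners cannot be told apart. Reads with several alignments were not counted, which leaves the levels of close paralogs and young repeats uncertain. A fragment over both a gene exon and a repeat was not assigned, and repeats cover a median of 6.87% of the exon length of tested genes and 7.51% for the interferon list.

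The ATAC files are the authors' peak lists, 1 per sample, with the columns that MACS2 writes and no header. Their signal value is a ratio, the fold enrichment of the peak summit over the local background as computed by the authors' peak caller. They also hold the -log10 p and -log10 q of each peak as deposited, and a display score, which in the deposited lists is the whole part of 10 times the -log10 q. The settings of the peak caller, the read depth and whether reads were shifted for the transposase are not given in the sources used here, so peaks were compared by presence, number and length only.

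Gene symbols were joined by gene ID for 54723 of 54752 genes. The libraries held 18929444 to 20809565 gene counts, mitochondrial genes took 2.24% to 5.05% of them, and TMM factors ran from 0.977 to 1.02. Repeat loci took 2.50% to 4.69% of all counts, of which 73.6% to 80.5% lay inside gene bodies. All 15 pairs of libraries were checked for duplicates by a chi-square test over genes, which gave 29.1 to 153 per degree of freedom, so no library repeats another. The first principal component of the gene values held 46.1% of the variance and the second 25.3%, and the first did not part the groups. On the second the control libraries lay at 57.4, -8.15 and 7.88 and the stress libraries at -8.70, -35.2 and -13.2, all below control, an order met in 10% of cases by chance. Repeat counts were summed to 1554 subfamilies by name.

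Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, the quasi-likelihood F test of stress against control and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The common biological coefficient of variation was 0.299. Repeat subfamilies were tested the same way with library sizes and TMM factors from the genes. The 33 gene lists, of microglial states, stress hormone response, chromatin silencing and marker genes of other cell types, were fixed before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, and members were also adjusted over the list alone. The preset test takes the correlation between genes of a list as small, so each call was set beside camera with an estimated correlation and fry.

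Peak numbers, covered length and width were compared by exact permutation of the 6 samples, where 3 against 3 cannot give a p under 0.1. Peaks were merged over samples at an overlap of 1 bp with bedtools 2.31.1, and a region was called stress-only or control-only when all 3 samples of the group and none of the other had a peak. Transcription starts were the outermost annotated 5' end of each gene, with a window of 500 bp. Genes starting within 50 kb of such a region were tested against all other tested genes with camera. Scripting used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

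Genes and regions to name were chosen by a rule fixed beforehand. It takes the 10 higher and 10 lower genes with the smallest adjusted p that pass with groups that do not overlap or, if fewer than 5 pass, the 5 with the smallest p per direction. It adds up to 4 members of each list, those passing by p or else those with the largest absolute fold change and a mean log2 CPM of at least 3, and fixed reference genes, of which the report gives P2ry12, Tmem119, Cx3cr1, Csf1r, Itgam, Trem2, Apoe, Fkbp5, Nr3c1, Il1b and Tnf. It also takes 5 subfamilies per direction by p, the 5 stress-only and 5 control-only regions with the highest mean score percentile within their lists, and peaks at the starts of the reference genes. Names outside this rule are said to be chosen after their values were seen, and the host genes and loci of called subfamilies were chosen in that way.

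The labels do not say that the replicate numbers pair the samples. In the gene values, the deviations of a control and a stress library from their group means correlated at 0.46, 0.11 and 0.46 for numbers 1, 2 and 3, across genes, which are not independent replicates. All 3 lie above 0.1. Of the unlike numbers, control 2 with stress 1 at 0.30 and control 3 with stress 2 at 0.17 did so too. The remaining unlike numbers were negative: control 3 with stress 1 at -0.578, control 1 with stress 2 at -0.339, and stress 3 with controls 1 and 2 at -0.21 and -0.385. Like numbers thus tended to go together, but the data alone do not show where a pairing comes from. The number was therefore also used as a block, as an alternative. The others were DESeq2 1.42.0 factors and Wald test, upper-quartile factors, limma-voom, no low-count filter, no mitochondrial or unplaced genes, a false discovery rate of 0.1, subfamily factors, loci outside genes, a peak minimum of 5 for -log10 q, equal peak numbers (54363), 50% cover of a region, autosomes and X only, 10 and 100 kb, and each library left out in turn. Fits of the interferon list with a marker list as covariate and sums over broad repeat groups were added after seeing the data. All 10 splits of the 6 samples into 3 and 3 were run through the same tests.

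The tests were tested on simulated data with the spread and depth of these libraries. Of 2-fold changes edgeR recovered 12.1% among 15045 genes, and of 4-fold changes 68.4%, with 2 false calls, and with the dispersion divided by 4 it recovered 66.3% of 2-fold changes. Depth was not varied. Among 1001 subfamilies, with factors from the subfamilies themselves, it recovered 83.5% and 98.95%, with 7 false calls. The fit with factors from the genes, which gave the subfamily calls reported here, was not simulated, so these rates do not apply to those calls. Camera found the 1 shifted list of 33 and called 0 others, but the genes were simulated independently of each other. In the data the estimated correlation within the interferon list was 0.74. The simulation therefore could not show how often camera's preset test calls lists whose genes vary together. No sample was left out. Single repeat loci were not tested, and no locus of the genome was looked at beyond the annotation, since no genome sequence was used here.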

Results

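Microglia, the resident macrophages of the brain, were purified from male C57BL/6Slac mice aged 5 months, from brain tissue taken without the cerebellum and the olfactory bulb. Mice exposed to chronic mild stress, a rodent regimen of repeated mild stressors, were compared with control mice, and the design names 3 animals per group. The details of the regimen and of the purification are not given in the sources used here. Gene expression was measured by RNA-seq in 3 control and 3 stress libraries. Chromatin accessibility was measured in 3 control and 3 stress samples by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The RNA libraries held 18929444 to 20809565 counts in genes, and of 54752 annotated genes 15296 had enough counts to be tested. Repeat loci took a further 2.50% to 4.69% of all counts. The ATAC peak lists held 54363 to 66644 peaks per sample, and the read depth behind them is unknown. Values are means ± SD over n = 3 libraries per group, as CPM, counts scaled to a library's gene counts, for RNA, and fold changes are stress over control on the log2 scale.

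The RNA comparison asked which genes stood at other levels in the purified microglia after chronic mild stress. The libraries also held marker RNA of other cells, in amounts that varied between replicates. Over the 6 libraries choroid plexus and ependyma markers summed to 5169 to 43310 CPM and neutrophil markers to 631 to 10070 CPM. A difference between the groups therefore need not lie in microglia. Genes induced by type I interferon, the cytokine signal of antiviral defence, were lower in the stress libraries: all 24 measured members of the list fixed beforehand had a negative fitted log2 fold change, with a median of -2.14, a 4.41-fold higher level in control. Ifit2, an interferon-induced protein that binds viral RNA, stood at 169 ± 109.5 CPM in control and 19.4 ± 1.51 CPM in stress. Markers of T and NK cells, genes of antigen presentation and sensors of foreign nucleic acid were also lower in stress. Immediate early genes and homeostatic microglial genes were slightly higher, though their list means overlapped between the groups. These are calls of limma's camera with a preset correlation between genes, and none held with an estimated correlation (adjusted p = 0.848 for each). At the level of single genes, edgeR's quasi-likelihood test called 0 of 15296 genes at a false discovery rate of 0.05, with 567 at an unadjusted p under 0.05, and DESeq2's Wald test called 127.

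In 23 of the 24 interferon genes every stress library lay below every control library. By chance 10% of genes part the groups in one direction or the other with 3 libraries against 3. Over all 15296 tested genes 8.36% did so, 721 lower and 558 higher in stress. Genes of the interferon list vary together, with an estimated correlation of 0.74, so the 23 are not independent cases. Ifit3, a partner of Ifit2, stood at 215 ± 131 CPM in control and 29.8 ± 13.1 CPM in stress (log2 fold change -2.85, SE 0.60). Mx1, an interferon-induced GTPase, stood at 65.9 ± 41.1 CPM in control and 9.76 ± 0.691 CPM in stress (-2.75, SE 0.53). Oasl2, of the oligoadenylate synthetase family, stood at 179 ± 106 CPM in control and 29.5 ± 11.6 CPM in stress (-2.60, SE 0.57). Ifit2 itself (ENSMUSG00000045932.12, chromosome 19, 34550694 to 34576419, mm10) had a log2 fold change of -3.12 with an SE of 0.55. Irf9, chosen after its values were seen, had the smallest change of the list at -0.66. The mean log2 CPM of the list was 7.18, 5.54 and 6.92 in control replicates 1, 2 and 3 and 5.04, 4.45 and 4.55 in the stress replicates (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). In the same libraries the mean log2 CPM of the T and NK cell markers was 1.94, 0.57 and 2.48 against 0.34, 0.15 and 0.57, and that of the neutrophil markers was highest in control replicate 1, at 9.23, against 3.79 to 6.93 in the other libraries.

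**Figure D1:**
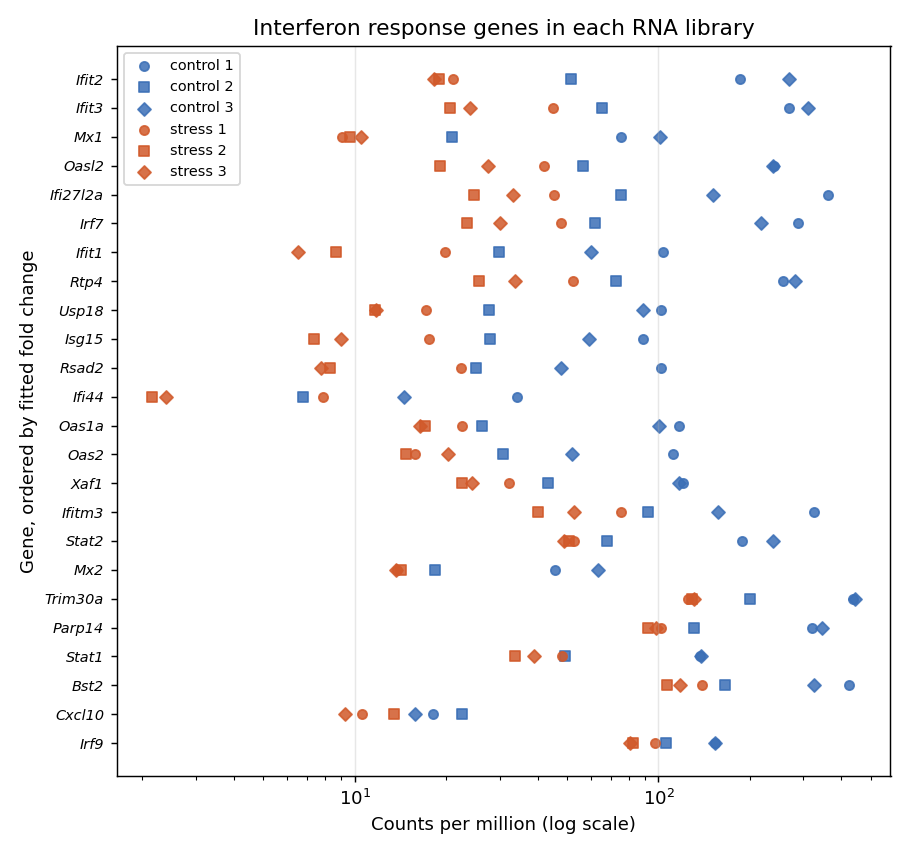
CPM (log scale) of the 24 genes of the fixed interferon list, 1 point per RNA library, with control in blue, stress in orange and the shape giving the replicate number. In 23 of the 24 genes the 3 stress points lie below the 3 control points, and control replicate 2 lies closest to the stress points in most of them.

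Limma's camera with its preset correlation called the interferon list lower (adjusted p = 3.04e-32), and all 24 members passed edgeR's test adjusted over the list alone, against 0 adjusted over all genes. With an estimated correlation the list had an adjusted p = 0.848 (unadjusted p = 0.0336), and limma's fry, which asks only whether the genes move one way, gave an adjusted p = 0.702 (unadjusted p = 0.0226). DESeq2's Wald test called 21 of the 24 genes lower.

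A further 6 groups were lower in stress by the preset camera test, each with an adjusted p = 0.848 with an estimated correlation. Of the T and NK cell markers all 10 tested members were fitted lower, with a median of -1.71 (adjusted p = 9.54e-09), or -1.06 without control replicate 3. Of these 6 passed adjusted over the list alone and in 3 the groups did not overlap. None reached a mean log2 CPM of 3, and their summed level was 53.2 ± 29.8 CPM in control and 19.4 ± 3.40 CPM in stress. In the list of antigen presentation 18 of 20 members were fitted lower with a median of -0.44 (adjusted p = 9.54e-09), and only Nlrc5 passed adjusted over the list alone. Nlrc5, the transactivator of MHC class I genes, stood at 58.3 ± 27.9 CPM in control and 13.7 ± 3.37 CPM in stress (-2.09, SE 0.40). Tap1, a peptide transporter, stood at 142 ± 66.3 against 63.98 ± 11.3 CPM (-1.15), and the class I genes H2-Q7 and H2-T23 had fold changes of -1.66 (-0.81 without control replicate 1) and -0.94. Of the nucleic acid sensing genes 14 of 18 were fitted lower with a median of -0.42 (adjusted p = 4.61e-06), and 8 passed adjusted over the list alone. Their median was -0.21 without control replicate 3 and -0.27 without stress replicate 1. Zbp1, a sensor of Z-form nucleic acid, stood at 56.1 ± 25.9 CPM in control and 8.38 ± 2.46 CPM in stress (-2.74, SE 0.42). Eif2ak2, the kinase PKR, stood at 74.3 ± 29.3 against 21.3 ± 0.411 CPM (-1.80), and the RNA helicases Dhx58 and Ddx58 had fold changes of -1.92 and -1.19. These 4 genes are themselves induced by interferon, though none is a member of the fixed interferon list.

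The cell cycle list was lower with a median of -1.05 and 19 of 20 members fitted lower (adjusted p = 4.05e-05). Its mean log2 CPM was 4.93, 3.04 and 3.84 in control replicates 1, 2 and 3. It was 3.30, 3.32 and 3.26 in the stress replicates, so control replicate 2 was the lowest library. The proliferation marker Mki67 stood at 54.97 ± 48.1 CPM in control and 18.5 ± 4.10 CPM in stress (-1.57). Top2a, the topoisomerase of dividing cells, stood at 43.8 ± 40.2 against 16.4 ± 1.67 CPM (-1.42), and Hmgb2 and Cenpf had fold changes of -1.06 and -0.75. Of the monocyte markers 8 of 9 were fitted lower, with a median of -1.75 (adjusted p = 0.00953). Ms4a4c, which also responds to interferon, stood at 37.00 ± 23.1 CPM in control and 7.72 ± 2.52 CPM in stress (-2.26, SE 0.48) and alone passed adjusted over the list. Ly6c2 stood at 134 ± 182 against 14.1 ± 9.34 CPM (-3.25, SE 1.19), and Plac8 had a fold change of -2.41. Of the markers of border macrophages, which line the meninges and vessels, 9 of 10 were fitted lower with a median of -0.36 (adjusted p = 0.0148): Siglec1, itself induced by interferon, -1.57, Cd163 -0.54, F13a1 -0.40 and Mrc1 -0.38. In all 3 lists the adjusted p was 0.848 with an estimated correlation. Their list means overlapped between the groups, with an exact permutation p of 0.4 for the cell cycle, 0.3 for monocytes and 0.3 for border macrophages. Without control replicate 1 the adjusted p of the preset test was 0.0621 for the cell cycle and 0.0907 for the monocyte markers, with medians of -0.27 and -0.42, and the monocyte markers also gave 0.173 without stress replicate 2. Without control replicate 1 Mki67, Top2a, Hmgb2 and Cenpf were at -0.59, -0.36, -0.26 and -0.32, and Ly6c2 and Plac8 at -1.03 and -0.86. The border macrophage list gave 0.0815, 0.361 and 0.0510 without control replicate 3, stress replicate 1 and stress replicate 2. Its median was -0.20 and -0.15 in the first 2 cases and -0.63 without stress replicate 3. With 1 library left out Siglec1 ranged from -2.32 to -0.76, Cd163 from -1.35 to 0.0897, F13a1 from -1.15 to -0.0705 and Mrc1 from -0.71 to -0.16.

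A set of 3 lists were higher in stress. Immediate early genes, which respond within minutes to a stimulus and also to the dissociation of tissue, had a median of 0.36 with 16 of 21 fitted higher (adjusted p = 1.37e-05). The transcription factor Egr2 stood at 21.5 ± 5.84 CPM in control and 43.2 ± 12.97 CPM in stress (1.01), Nr4a1 at 103 ± 8.99 against 176 ± 69.7 CPM (0.77), and the heat shock genes Hspa1a and Hspa1b had fold changes of 1.19 and 1.03 with SEs of 0.90 and 0.87. Without stress replicate 2 Nr4a1, Hspa1a and Hspa1b were at 0.41, 0.53 and 0.28. Homeostatic microglial genes had a median of 0.16 with 15 of 20 fitted higher (adjusted p = 0.00105). Slc2a5, a fructose transporter, stood at 448 ± 30.4 CPM in control and 598 ± 42.9 CPM in stress (0.42), Bin1 at 514 ± 47.04 against 673 ± 29.4 CPM (0.39), and Olfml3 and Fcrls both had fold changes of 0.39. The choroid plexus and ependyma markers, epithelial genes of the ventricles, had a median of 0.41 with 10 of 10 fitted higher (adjusted p = 0.0304). Ttr, the most abundant, stood at 15017 ± 11296 CPM in control and 21699 ± 10147 CPM in stress (0.53, with a range of 0.0626 to 1.21 when 1 library was left out). Kcne2, Folr1 and Kl had fold changes of 0.48, 0.44 and 0.38, with ranges of 0.00657 to 1.02, -0.0335 to 1.04 and -0.0186 to 0.70 when 1 library was left out. The list means overlapped between the groups in all 3 lists. The exact permutation p was 0.3 for the immediate early, 0.3 for the homeostatic and 0.5 for the choroid list. None of the named members passed adjusted over its list alone, and the adjusted p of all 3 lists was 0.848 with an estimated correlation. Without control replicate 1 the homeostatic list gave 0.123, and 0.0510 without stress replicate 2, while the choroid list gave 0.918, 0.267 and 0.168 without control replicate 3, stress replicate 1 and stress replicate 2. Its median then was 0.03, 0.12 and 0.47, against 0.74 without control replicate 2 and 0.63 without stress replicate 3. The homeostatic median was 0.08 without control replicate 1 or control replicate 2 and 0.27 without control replicate 3, and the immediate early median 0.55 without control replicate 2.

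**Figure D2:**
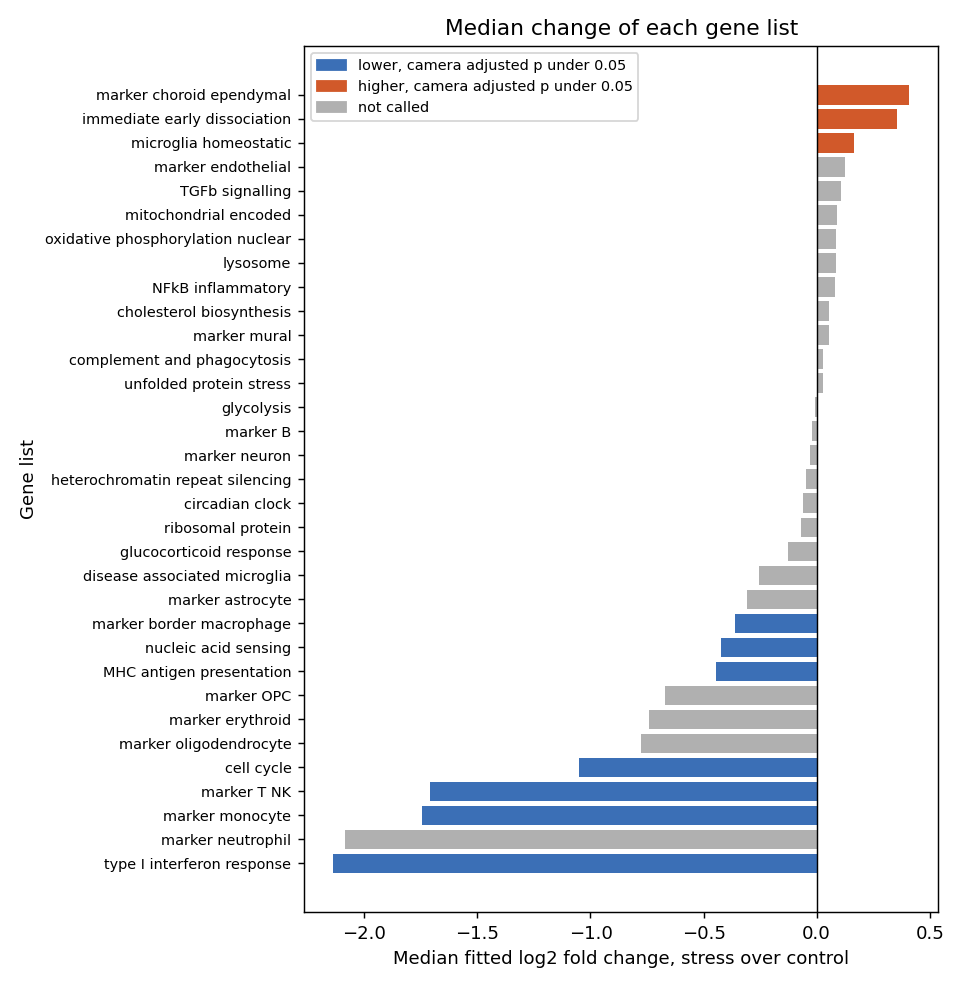
Median fitted log2 fold change, stress over control, of each of the 33 fixed gene lists, with blue and orange bars for lists called lower and higher by camera with its preset correlation. The interferon list has the lowest median at -2.14, and the neutrophil markers, at -2.08, were not called.

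The other 23 lists were not called by the preset test; their medians follow with the adjusted p in brackets. Neutrophil markers had a median of -2.08 (adjusted p = 0.0965). The granule genes Camp, Ngp, Lcn2 and Ltf had fold changes of -2.71, -2.27, -2.11 and -2.09, and each was higher in stress without control replicate 1, at 1.21, 1.16, 0.66 and 1.21. Genes of disease-associated microglia had a median of -0.26 (0.0528), with Spp1 at 27.8 ± 19.3 against 9.65 ± 1.41 CPM (-1.53), Clec7a at 56.6 ± 12.1 against 35.98 ± 1.36 CPM (-0.65), Lgals3 at -1.33 and Axl at -0.87. Without control replicate 3 Spp1 and Axl were at -0.79 and -0.53, and without control replicate 1 Lgals3 was at -0.29. Glucocorticoid response genes, the targets of the adrenal stress hormone, had -0.13 (0.126): Tsc22d3 stood at 596 ± 34.4 against 442 ± 71.1 CPM (-0.43), and Ddit4, Sult1a1 and Zbtb16 had fold changes of -0.55, -0.45 and -0.56, which ranged over -0.78 to -0.20, -0.90 to -0.18 and -1.05 to 0.19 with 1 library left out. NF-kB and inflammatory genes had 0.08 (0.733), with Ccl5 at -1.55, Ccl4 at 0.46, Il6 at -0.46 and Ccl2 at 0.38. Ccl5 was at -0.73 without control replicate 3, Il6 at -0.24 without stress replicate 1, and Ccl4 and Ccl2 at 0.20 and -0.0277 without stress replicate 2. Complement and phagocytosis genes had 0.03 (0.737), with C3 at 58.7 ± 74.7 against 19.03 ± 10.98 CPM (-1.62, but 0.29 without control replicate 1), C4b at -0.79 (-1.37 to -0.39 with 1 library left out) and Fcgr1 at -0.43. Heterochromatin and repeat silencing genes had -0.05 (0.183), with Daxx and Morc3 both at -0.45 and Atrx at -0.35, and TGF-beta signalling genes had 0.11 (0.165), with Tgfb1 at 291 ± 45.95 against 391 ± 20.4 CPM (0.43).

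Metabolic and housekeeping lists lay near 0: ribosomal proteins -0.07 (0.0528), nuclear oxidative phosphorylation genes 0.09 (0.0639), mitochondrially encoded genes 0.09 (0.183), lysosomal genes 0.08 (0.135), glycolysis -0.01 (0.460), cholesterol synthesis 0.06 (0.970), the unfolded protein response 0.03 (0.538) and the circadian clock -0.06 (0.970). Among the markers of other brain and blood cells, oligodendrocyte genes had -0.78 (0.0895), oligodendrocyte precursors -0.67 (0.470), astrocytes -0.31 (0.183), neurons -0.03 (0.970), endothelium 0.13 (0.428), mural cells 0.06 (0.385), B cells -0.02 (0.349) and erythroid cells -0.74 (0.419). The immunoglobulin gene Igkc stood at 77.2 ± 39.9 against 24.01 ± 11.4 CPM (-1.68), and the myelin gene Mal had a fold change of -1.12 (-0.73 without control replicate 3). With the replicate number as a block 5 of these lists passed: ribosomal proteins (adjusted p = 0.0419), oxidative phosphorylation (adjusted p = 0.0372), oligodendrocytes (adjusted p = 0.0387), the glucocorticoid response (adjusted p = 0.0238) and astrocytes (adjusted p = 0.0153). With an estimated correlation each of these 5 had an adjusted p = 0.802 in the same fit. In 7 uncalled lists the median, the mean and the test differed in sign: the mean was 0.02 for glycolysis, 0.00 for the clock, -0.05 for the unfolded protein response, -0.08 for the inflammatory genes, -0.16 for complement, 0.02 for cholesterol synthesis, where the test pointed lower, and -0.26 for neurons, where it pointed higher.

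No single gene passed: edgeR's quasi-likelihood test gave 567 genes with an unadjusted p under 0.05, of which 126 were higher and 441 lower in stress, and the smallest adjusted p among the genes named next was 0.432. The 5 genes higher in stress with the smallest p included Fscn1, which bundles actin, at 379.6 ± 32.6 CPM in control and 562 ± 53.1 CPM in stress (log2 fold change 0.57, SE 0.13), and Inka1, an inhibitor of a p21-activated kinase, at 41.4 ± 2.89 against 60.3 ± 3.50 CPM (0.54). The others were Ctnnd2, the neuronal delta-catenin (0.82), Tmem202 (2.23) and the immunoglobulin segment Igkv13-85. Igkv13-85 had 1 count in control and 41 counts in stress, so no fold change is given. The 5 genes lower in stress with the smallest p included Gbp6, a guanylate-binding protein, at 5.37 ± 0.741 CPM in control and 0.770 ± 0.123 CPM in stress (-2.79, SE 0.31), and Tgtp2, an immunity-related GTPase, at 53.97 ± 17.4 against 9.77 ± 2.97 CPM (-2.46, SE 0.30). Trim12c (-1.33), Ifi206 (-2.55) and Ifi203 (-1.52) made up the rest. All 5 belong to families of close paralogs whose shared reads were not counted, so their levels are uncertain.

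The microglial identity genes had small fitted fold changes. P2ry12, a purinergic receptor of resting microglia, stood at 3927 ± 279 CPM in control and 4772 ± 615 CPM in stress (0.28, SE 0.16) and Tmem119 at 2369.9 ± 273 against 2527 ± 262 CPM (0.09). Cx3cr1, the fractalkine receptor, stood at 1004 ± 201 against 953 ± 182 CPM (-0.07). Csf1r, Itgam, Trem2 and Apoe had fold changes of 0.17, 0.18, 0.20 and -0.06. With 1 library left out Tmem119 ranged from 0.0363 to 0.191, Csf1r from 0.0812 to 0.288, Itgam from 0.125 to 0.277 and Trem2 from 0.0838 to 0.331. Of the genes tied to stress hormones, Fkbp5, a target of the glucocorticoid receptor, stood at 426 ± 138 CPM in control and 326 ± 166 CPM in stress (-0.39, SE 0.45) and Nr3c1, the receptor itself, at 287 ± 16.6 against 263 ± 12.5 CPM (-0.13). The cytokine genes Il1b and Tnf had fold changes of -0.08 and 0.27 with SEs of 0.45 and 0.31, and none of these genes passed edgeR's test. With 1 library left out Fkbp5 ranged from -0.68 to -0.0261, Il1b from -0.46 to 0.53, Tnf from 0.0592 to 0.63, Cx3cr1 from -0.23 to 0.0531 and Apoe from -0.15 to 0.0676.

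The count of 0 came from edgeR with TMM factors, and limma-voom, 2 other sets of factors, no low-count filter and a false discovery rate of 0.1 also gave 0. DESeq2's Wald test gave 6 higher and 121 lower genes, 21 of them in the interferon list, and edgeR gave 2 lower genes with the replicate number as a block (Tgtp2, adjusted p = 0.0221, and Zbp1, adjusted p = 0.0439) and 66 lower genes without control replicate 2. When the 6 libraries were split into groups of 3 in the 9 other ways, DESeq2 called 0 to 655 genes and the preset camera test 7 to 16 lists, so the 127 genes and the 10 lists of the real groups were not the highest counts. Among the 3 other splits that part all number pairs, as the real one does, DESeq2 called at most 20 genes and camera at most 13 lists.

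**Figure D3:**
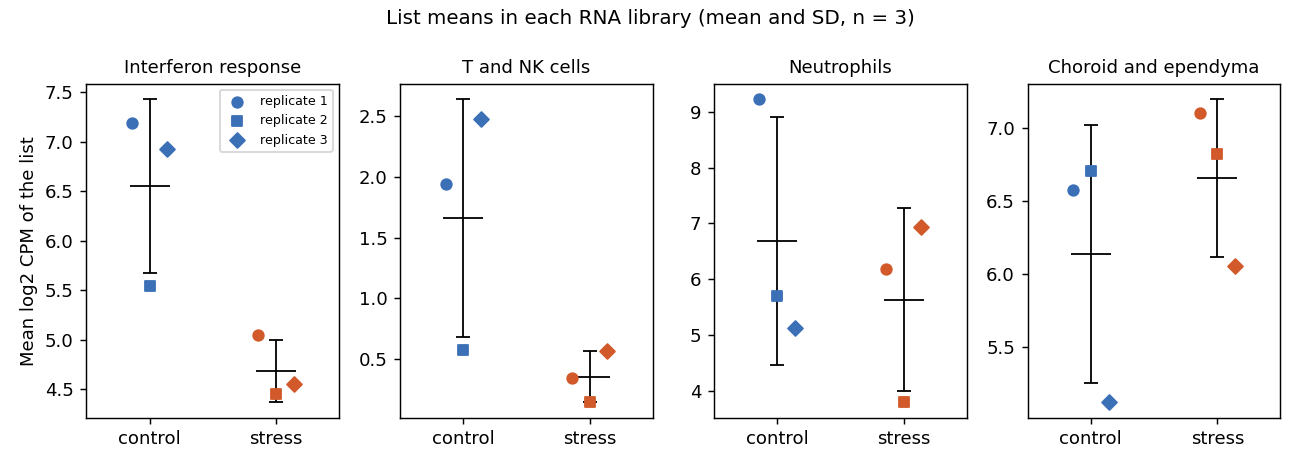
Mean log2 CPM of the interferon, T and NK cell, neutrophil and choroid lists in each of the 6 RNA libraries, with control in blue, stress in orange and bars for the mean and SD. The interferon list parts the groups, with control replicate 2 at 5.54 next to the highest stress library at 5.04.

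Repeats are the remains of transposable elements and simple sequences between and inside genes, and the count tables held 5147736 repeat loci beside the genes. Summed into subfamilies and scaled by the genes, edgeR called 13 of 1033 tested subfamilies lower in stress and 0 higher. Scaled by the subfamilies themselves it called 0, with a median log2 fold change of 0.00711, and the sum of all repeat counts did not pass (exact permutation p = 0.4). The called ones were mostly endogenous retroviruses and L1 elements, and ERVB2_1-I_MM-int, the inner part of an endogenous retrovirus, fell from 39.4 CPM in control to 8.32 CPM in stress. Most of the drop lay in a few loci inside genes that were themselves lower in stress, such as Ifi213 and Trim30a.

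ERVB2_1-I_MM-int stood at 39.4 ± 18.1 CPM in control and 8.32 ± 3.80 CPM in stress, a log2 fold change of -2.24 (SE 0.29, adjusted p = 1.15e-11). ERVB5_1-I_MM-int stood at 11.5 ± 6.90 CPM in control and 2.63 ± 0.560 CPM in stress (-2.12, adjusted p = 5.89e-09), and IAPEY3-int, from the intracisternal A particle group, at 19.2 ± 8.85 against 4.82 ± 1.88 CPM (-2.00, adjusted p = 7.44e-09). The L1 subfamily L1Md_Gf stood at 17.9 ± 9.77 against 5.55 ± 2.14 CPM (-1.69, adjusted p = 2.69e-06) and ERVB4_1B-I_MM-int at 7.94 ± 4.99 against 2.93 ± 1.58 CPM (-1.44, adjusted p = 0.000769). The other 8 were L1_Mm, MMTV-int, IAP1-MM_I-int, RLTR53B_Mm, RLTR10, SRV_MM-int, (GTCTG)n and RLTR50B. The 5 subfamilies higher in stress with the smallest p did not pass: MURVY-int at 1.36 ± 0.336 against 2.24 ± 0.446 CPM (0.71, adjusted p = 0.491), RLTR13B1 at 15.7 ± 1.45 against 22.3 ± 3.44 CPM (0.51), (CTAGGG)n (0.84), RLTR9A2 (0.73) and MLT2F (0.42). Of the 1033 subfamilies 927 were fitted lower, with a median of -0.32, against 499 of 1028 and a median of 0.00711 with factors from the subfamilies. With factors from the genes the median was -0.17 without control replicate 3 and -0.16 without stress replicate 1, and the repeat share of all counts ran from 2.50% in stress replicate 1 to 4.69% in control replicate 3.

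The 13 subfamilies had 14724 loci, of which 751 held any count, and together they dropped by 121 CPM. Inside annotated genes lay 88.4% of that drop, and 80.3% inside genes with a fitted log2 fold change below -0.5. Those genes also held 68.3% of the control CPM of these subfamilies, so an even drop at all loci would have put 68.3% there. The 10 loci with the largest drop held 70.2% of it. The first was an ERVB2_1-I_MM-int copy in Ifi213 (chromosome 1, 173567201 to 173572494) with 34.6 CPM in control and 7.44 CPM in stress, and a neighbouring IAPEY3-int copy in the same gene (chromosome 1, 173573077 to 173580305) had 14.9 CPM in control and 2.34 CPM in stress. An L1_Mm copy in Trim30a (chromosome 7, 104412877 to 104415655) had 18.8 CPM in control and 4.63 CPM in stress, and an L1Md_Gf copy in Trim30d (chromosome 7, 104475378 to 104477897) had 16.2 CPM in control and 4.58 CPM in stress. In 7 of the 13 subfamilies at least 50% of the drop lay inside such lower genes, and in the other 6, ERVB4_1B-I_MM-int, MMTV-int, IAP1-MM_I-int, SRV_MM-int, (GTCTG)n and RLTR50B, less than 25% did. The strongest ERVB4_1B-I_MM-int locus (chromosome 18, 60283764 to 60286772) lay 6608 bp and the strongest RLTR50B locus 3467 bp from F830016B08Rik, a gene with a log2 fold change of -2.85.

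The 13 calls come from edgeR with library sizes and factors from the genes, where 109 subfamilies had an unadjusted p under 0.05. With factors from the subfamilies 0 were called. The fold changes and the prior degrees of freedom of the spread (infinite with the first, 4.74 with the second) changed together. With an infinite value each subfamily takes the shared fitted spread and none of its own, so the very small adjusted p rest on that. Which of the changes removed the calls was not tested. With factors from the subfamilies ERVB2_1-I_MM-int had -1.92 (SE 0.32, adjusted p = 0.126), against -2.24 (SE 0.29, adjusted p = 1.15e-11) with factors from the genes. With only loci outside genes 0 of 636 were called: ERVB4_1B-I_MM-int was then at -1.87 (adjusted p = 0.299), IAPEY3-int at -0.35 and L1Md_Gf at -0.76 (adjusted p = 0.995 for both). DESeq2's Wald test gave 3 and the replicate block 36, leaving out control replicate 1, control replicate 3, stress replicate 1, stress replicate 2 or stress replicate 3 gave 6, 6, 8, 4 and 23, and the 9 other ways to split the libraries gave 0 to 31 called subfamilies.

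ATAC peaks mark stretches of open chromatin, and their number and length per sample were compared between stress and control microglia. The stress samples had somewhat more and wider peaks, but the groups overlapped and no difference passed. Peak numbers were 57694 ± 3705 in control and 60528 ± 5521 in stress (exact permutation p = 0.6, where 3 against 3 cannot give less than 0.1), and without stress replicate 2 the difference, stress minus control, was -223.7. The covered length was 27.2 ± 3.03 Mb against 29.9 ± 2.88 Mb (exact permutation p = 0.4), and the median peak width 399 ± 18.2 bp against 425 ± 6.56 bp (exact permutation p = 0.2). Summits within 500 bp of a transcription start made up 20.5% of peaks in control and 19.95% in stress, and summits inside repeats 15.9% and 16.1%. The authors' median fold enrichment at the summit was 7.81 and 7.91. With stress and control samples of the same number set against each other, stress had the longer covered length in 3 of 3 pairs and the higher peak number in 2 of 3. An exact sign-flip test over 3 pairs cannot give a p under 0.25.

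The chromatin comparison then asked which regions were open in all samples of one group and in none of the other. Most regions were shared: of 77747 regions in the union 42138, or 54.2%, had a peak in all 6 samples. A peak in all 3 stress and no control sample was found at 353 regions, and the reverse at 102. Both sets were weak peaks, with a median score percentile of 14.9 and 14.8 within their lists. Transcription starts lay within 500 bp of 21 stress-only and 7 control-only regions.

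Among the stress-only regions the highest ranked lay 1256 bp from the start of Abi1, an adaptor of actin remodelling (chromosome 2, 23041497 to 23041760), with the authors' fold enrichments of 4.46, 4.84 and 4.51 in the 3 stress samples. The next were a region in an intron of E130307A14Rik (chromosome 10, 39686786 to 39687133), with 9.25, 9.50 and 7.49, and a region between genes (chromosome 10, 40519610 to 40519889), with 4.86, 4.70 and 6.30. A region in both Gm12014 and Plek, the platelet substrate pleckstrin, overlapped an exon (chromosome 11, 17019388 to 17019690) and had 6.94, 8.45 and 9.22. A region in an intron of Gm40438 (chromosome 12, 71359708 to 71360056) had 8.09, 7.39 and 7.49. Of the control-only regions the first lay 39055 bp from the start of Abcg1, a cholesterol exporter (chromosome 17, 31018327 to 31018643), with fold enrichments of 6.45, 8 and 7.08 in the 3 control samples. The others were a region between genes (chromosome 10, 17215042 to 17215427), with 8.74, 8.22 and 7.33, and a region in an intron of Mapk12 close to Hdac10 (chromosome 15, 89131400 to 89131666), with 6.22, 4.76 and 5.93. A region 3102 bp from the class I gene H2-T24 (chromosome 17, 36023662 to 36023944) had 5.89, 4.47 and 4.49, and a region in an intron of Rcor1 (chromosome 12, 111088327 to 111088618) had 6.47, 8.67 and 7.24. At the outermost annotated start of the reference genes a peak was found in all 6 samples for P2ry12, Tmem119, Csf1r, Itgam, Apoe, Fkbp5, Nr3c1 and Tnf. Trem2 had one in 5 samples, without control replicate 3, and Cx3cr1 and Il1b had 0, where only that outermost start was looked at.

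The balance between the 2 sets differed with the peaks used. With the same number of peaks from every sample, 54363, there were 201 stress-only and 211 control-only regions, but 413 and 59 with a -log10 q of at least 5 and 506 and 127 where peaks had to cover 50% of a region. Over the 9 other splits of the 6 samples the 2 sets differed by 14 to 779 regions, against 251 for the real groups, and no test for a single region can pass with presence in 3 against 3.

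**Figure D4:**
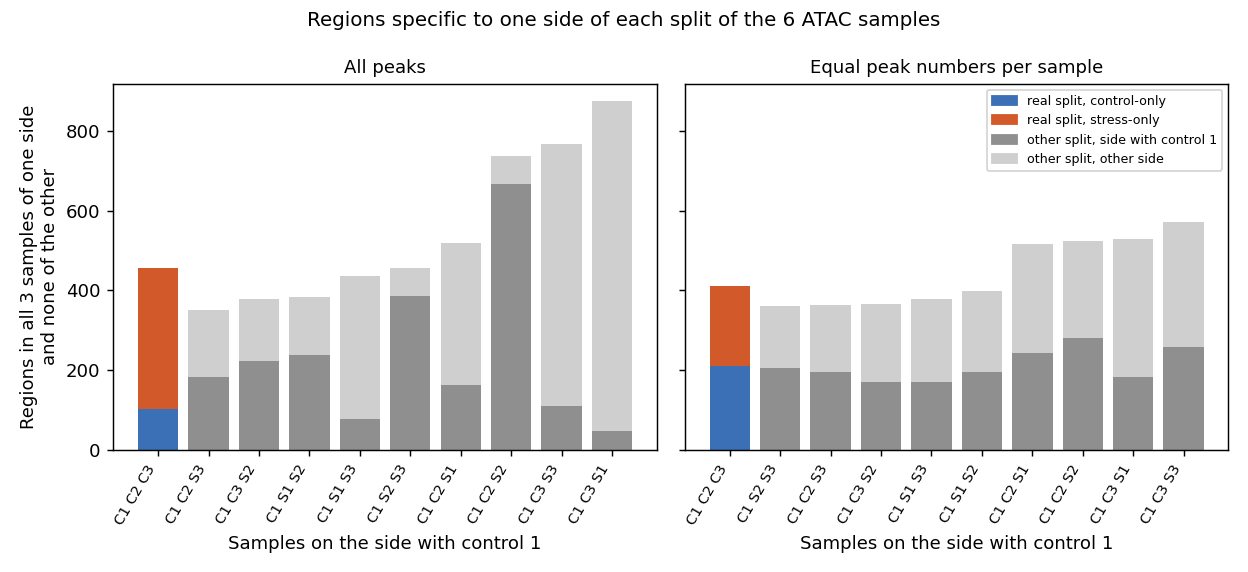
Number of regions found in all 3 samples of one side and in none of the other, for each of the 10 ways to split the 6 ATAC samples 3 against 3, with all peaks and with equal peak numbers. With all peaks the split into stress and control has 455 regions, fewer than the largest other split with 875.

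The last comparison joined the assays and asked whether genes close to group-specific regions were expressed at other levels after stress. No such difference was found: 443 tested genes with a start within 50 kb of a stress-only region had a median log2 fold change of 0.02, and 108 genes near control-only regions had -0.04. Of the first set 236 were fitted higher and of the second 46. Limma's camera gave an adjusted p = 0.703 for both. No set passed at 10 kb or 100 kb, with equal peak numbers, with an estimated correlation (adjusted p = 0.847 for both) or without any 1 library. The 9 other splits of the libraries gave at most 1 called set.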

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

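All alternatives here were chosen before the data were examined except the covariate fits of the interferon list and the broad repeat groups; the latter give no value against a threshold, since their exact test cannot go under 0.1. The replicate number as a block changed no call other than those given with it. Among the fold changes of single genes and subfamilies, 1143 kept their direction and their side of the threshold, 35 passed where they had not, 13 no longer passed and 18 changed sign. In simulated data edgeR recovered 12.1% of 2-fold changes, and 66.3% with the dispersion divided by 4, while depth was not varied, and for ATAC the depth is unknown. With the markers of T and NK cells, neutrophils, monocytes or the choroid plexus as a covariate, camera's adjusted p of the interferon list was 1.62e-08, 5.99e-30, 3.18e-26 and 1.68e-15 with the preset correlation. With an estimated correlation the adjusted p of these 4 fits was 0.836, 0.873, 0.954 and 0.766. The median log2 fold change of the list was -0.88, -1.70, -1.39 and -1.87 in them, against -1.98 without a covariate, and the T and NK covariate itself correlated at -0.749 with the group.

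For single genes edgeR's count of 0 was 0 with other factors, no filter, no mitochondrial genes, limma-voom and a false discovery rate of 0.1, while DESeq2 called 6 genes higher and 121 lower and the replicate block 2 lower. Leaving out each library in turn gave 0 to 66 lower genes, with 66 only without control replicate 2. The 10 called lists became 0 higher and 0 lower with an estimated correlation and 0 higher and 0 lower with fry, and 11 lower with the replicate block. Leaving out 1 library gave 1 to 7 higher and 6 to 11 lower lists. With an estimated correlation the adjusted p was 0.848 for each of the homeostatic, interferon, immediate early, antigen presentation, cell cycle, nucleic acid sensing, border macrophage, monocyte, T and NK, and choroid lists. With fry the adjusted p was 0.845 for the homeostatic, immediate early, border macrophage and monocyte lists, 0.702 for the interferon, antigen presentation and T and NK lists, 0.773 for nucleic acid sensing, 0.888 for the cell cycle and 0.922 for the choroid list. The interferon, antigen presentation, T and NK, nucleic acid sensing and immediate early lists kept their preset call without any 1 library. The adjusted p ranged from 6.59e-05 to 0.123 for the homeostatic list (not called without control replicate 1 or stress replicate 2), 2.05e-10 to 0.0621 for the cell cycle (control replicate 1), 4.77e-05 to 0.361 for border macrophages (control replicate 3, stress replicate 1 or stress replicate 2), 0.000789 to 0.173 for monocytes (control replicate 1 or stress replicate 2) and 0.000158 to 0.918 for the choroid list (control replicate 3, stress replicate 1 or stress replicate 2). The cause was not tested.

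Of 85 genes whose alternatives were run 13 changed sign at least once, none of which passed the test. Irf9 and Gzma among the 85 were chosen after their values were seen. Leaving out 1 library, the log2 fold change ran over -3.26 to 1.21 for Camp, -2.92 to 1.16 for Ngp, -3.19 to 0.66 for Lcn2, -2.81 to 1.21 for Ltf and -2.16 to 0.29 for C3, each positive without control replicate 1. Without control replicate 3 the sign changed for Zbtb16 (-1.05 to 0.19), Cd163 (-1.35 to 0.0897), Folr1 (-0.0335 to 1.04), Kl (-0.0186 to 0.70), Cx3cr1 (-0.23 to 0.0531, also without stress replicate 1) and Apoe (-0.15 to 0.0676, also without stress replicate 2), without stress replicate 2 for Ccl2 (-0.0277 to 0.61), and without control replicate 2 for Il1b (-0.46 to 0.53). Il1b was also at 0.15 with the replicate block and 0.16 with limma-voom. The cause was not tested.

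For repeat subfamilies the 13 lower calls became 0 with factors from the subfamilies, where the fold changes and the fitted spread changed together, 0 of 636 with loci outside genes (ERVB4_1B-I_MM-int then at -1.87, against -1.44 with all loci), 36 with the replicate block and 3 with DESeq2, and stayed at 13 with RLE factors. Leaving out 1 library gave 4 to 23 lower and 0 to 1 higher, the 1 without control replicate 3. RLTR13B1 was at -1.05 with loci outside genes. The difference in ATAC peak number ranged from -224 to 5143 with 1 sample left out, negative only without stress replicate 2. Equal peak numbers gave 201 stress-only and 211 control-only regions and a stricter peak threshold 413 stress-only and 59 control-only regions, and 50% cover 506 and 127. Leaving out 1 sample gave 561 to 1240 stress-only and 161 to 498 control-only regions, where fewer samples must share a region. For genes near stress-only regions the direction changed at 10 kb (adjusted p = 0.907), where fewer genes were tested, and for control-only regions it changed without control replicate 1, control replicate 3 or stress replicate 1, over a range of 0.265 to 0.998, and no set passed in any alternative.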

Other observations

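Chosen only after results were seen were the gene families, the broad repeat groups and the share of the drop for each subfamily. So were all splits except those for genes near regions and those for group-specific ATAC regions. For the latter, only the comparison of the difference between the 2 sides came after. The fits without control replicate 1, with factors from the subfamilies and with equal peak numbers were set before the data were examined, but taken as tests of an explanation only after their results were seen. The gene families are known to respond to interferon, lie largely outside the fixed list and were not tested as groups. All 9 tested guanylate-binding proteins had a negative fitted log2 fold change, with a median of -1.52, as had all 7 immunity-related GTPases (median -1.52), 11 genes of the Ifi200 family (median -2.40), 7 Schlafen genes (median -2.25) and 8 oligoadenylate synthetases (median -2.19), of which 3 belong to the fixed list. In all of them except 1 GTPase every stress library lay below every control library, but genes of a family vary together and the families were picked with such values in view, so no chance rate applies. The member with the smallest change stood at -0.82, while other scaling factors moved the median of all genes to at most 0.02. These are families of close paralogs, so the level of a single member is uncertain, and none passed edgeR's test over all genes.

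Of the 24 starts of the interferon genes 18 had an ATAC peak in all 6 samples and those of Ifi44 and Ifitm3 in none, so peak presence could hardly differ between the groups. The others were Oas2, with a peak in control replicates 1 and 2, Isg15 in control replicate 3, Parp14 in all samples but stress replicate 1, and Rtp4 in control replicate 2 and stress replicates 2 and 3. All 25 lysosomal genes had a peak in every sample, as had all 20 cell cycle genes, while of 12 T and NK markers 1 had a peak in control replicate 2 and 0 in the other samples. Summed over broad groups, repeat counts were 40047 ± 7282 CPM in control and 33043 ± 6744 CPM in stress (exact permutation p = 0.4). Within the number pairs they were lower in stress in 3 of 3 (exact sign-flip p = 0.25, the smallest that 3 pairs allow). The ratio of stress to control lay between 0.777 for L1 and 0.860 for the remaining names, with IAP elements at 0.789 (exact permutation p = 0.1, the smallest possible, adjusted p = 0.545).

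The 10 tested T and NK cell markers, none of them in the interferon list, summed to 53.2 ± 29.8 CPM in control and 19.4 ± 3.40 CPM in stress. Their most abundant, Gzma, chosen after its values were seen, stood at 12.5 and 5.15 CPM. The interferon list summed to 3323 ± 1623 CPM in control and 916 ± 148 CPM in stress. How far the purification removed T and NK cells is not given in the sources used here.

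Interferon-response genes were lower in the stress libraries, with a median log2 fold change of -2.14 over 24 genes. The tables argue against neutrophil and monocyte RNA in control replicate 1 as the whole cause, since without that library the median was -1.60 and camera's adjusted p 4.62e-27 (adjusted p = 0.888 with an estimated correlation). T and NK cell RNA in the control libraries stays open. With their marker mean as a covariate the median was -0.88 (mean -0.83, SE 0.50), against -1.98 on the same log2 CPM scale without it. That covariate itself correlated at -0.749 with the group, so the fit cannot part the 2. The 10 markers summed to 53.2 CPM in control and 19.4 CPM in stress, the interferon list to 3323 and 916 CPM. To supply the whole drop, RNA of these cells would have to hold far more of the interferon genes than of their own markers. Only 1 of the 10 splits of the 6 libraries, the real one, gave a difference in the list mean as large (1.87, against 1.53 in the highest other split and 1.14 among those that part all 3 number pairs), and 10 splits are too few for a share under 0.05. A lower interferon response of microglia after chronic mild stress may account for the pattern and also stays open, untested. The list mean was 7.18 and 6.92 in control replicates 1 and 3. It was 5.54 in control replicate 2, against 5.04, 4.45 and 4.55 in stress replicates 1, 2 and 3. Whether the stress libraries stood low or control replicates 1 and 3 high cannot be told from 3 libraries per group.

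Of the repeat subfamilies 13 were called lower in stress. With factors from the subfamilies the median log2 fold change of the 13 was -1.23, against -1.62 with factors from the genes, and none was then called. The median of all tested subfamilies moved from -0.32 to 0.00711. The 13 were picked for their drop in the same data, so their median had to stay low. It therefore does not weigh a library-wide lower share of repeat counts as a cause. Transcripts of lower-expressed genes that hold the loci may account for part of the drop, since 80.3% of it lay inside genes with a log2 fold change below -0.5, against 68.3% if all loci had dropped evenly. In 6 of the 13 less than 25% of the drop lay there, which argues against such transcripts for these 6, but for ERVB4_1B-I_MM-int and RLTR50B a longer transcript of the lower gene F830016B08Rik, 6608 and 3467 bp from their strongest loci, stays open, as does a change in the elements themselves, untested. In 2 of the 10 splits as many subfamilies were called (13, against 31 in the highest other split and 5 among those that part all 3 number pairs), and 10 splits are too few for a share under 0.05.

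Stress samples had more group-specific accessible regions than control samples, 353 against 102. Longer peak lists in the stress samples are a candidate explanation: with equal numbers of peaks the ratio of stress-only to control-only regions was 0.953. Equal numbers also drew the sides together in most other splits, in the most uneven from a difference of 779 to 162, so this ratio decides little. The stress lists were longer only on average, with 55911 peaks in stress replicate 1 against 57033 and 61685 in control replicates 1 and 2. With a -log10 q of at least 5 the sets held 413 and 59 regions. Whether deeper sequencing or more open chromatin made the lists longer cannot be read from peak lists without depth, and an effect of stress on chromatin stays open, untested. In 6 of the 10 splits the 2 sets differed by as many regions (251, against 779 in the highest other split), and 10 splits are too few for a share under 0.05.

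For the other counts 10 splits are also too few for a share under 0.05. EdgeR's test called 0 genes in the real split and 0 in each other, so all 10 gave as many, against 567 genes at an unadjusted p under 0.05 and 127 by DESeq2 in the real split. DESeq2 called as many in 2 of the 10 splits, with 655 in the highest other one and 20 in the highest of those that part all 3 number pairs. The split with 655 sets control replicates 1 and 2 and stress replicate 1 against the rest, which points to a structure of the samples apart from stress. Chosen after their values were seen, the endothelial markers had a mean log2 CPM of 6.25, 6.15 and 6.71 in these 3 libraries. They stood at 4.25, 5.56 and 4.84 in control replicate 3 and stress replicates 2 and 3. The mural markers were at 4.12, 3.93 and 4.45 against 2.40, 3.72 and 2.93. Whether RNA of such cells made the split was not tested. Camera with its preset correlation called as many lists in 7 of the 10 splits, 10 in the real one and 16 in the highest other (13 among those that part all 3 number pairs), so its calls do not set stress and control apart from other groupings. For genes near group-specific regions all 10 splits gave as many called sets, 0 in the real one and 1 in the highest other.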
